A study of Homo sapiens with 60 samples.

How the data were processed

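RNA was measured by sequencing in 60 libraries of SW1783, a human astrocytoma cell line (a glial tumour line held by the ATCC), grown in Leibovitz's L-15 medium, whose sugar is galactose. Cells had been exposed for 24 h to an extract of a herbal medicine or to the vehicle, dimethyl sulfoxide. The sample labels give the vehicle as 0.1% and the series' design text gives another concentration, so the value used in the experiment stays open. The libraries were made with a strand-specific kit and read in pairs on an MGI sequencer. The deposited table holds expected counts per gene made by the authors with RSEM. Per the submitters' processing notes, reads were checked with FastQC 0.11.9, trimmed with Trim Galore 0.6.5, aligned to hg38 with STAR 2.7.3a and counted with RSEM 1.3.3. The annotation release and the strand setting of the counting step are not given in the sources used here. Expected counts share a read that matches several genes between them, so 10.86% of the values were not whole numbers; all values were rounded to whole numbers before the count models were fitted.

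The table held 60675 Ensembl genes, of which 57055 have a position in GENCODE release 29 and 56558 carry a current symbol. Total counts per library lay between 18.73 and 35.52 M (median 25.79 M). The first part of the library names separates the libraries into 5 sets, and the 3 vehicle libraries, with 18.73 to 20.47 M counts, make up a set of their own. The sample titles place all libraries, vehicle and treated, in the same batch (BatchC). The sources used here do not say what the first part of the name stands for. The treated sets spanned 19.02 to 32.34, 20.71 to 35.52, 18.9 to 29.65 and 21.13 to 27.38 M. A check of 51 pairs of libraries of the same group found no copies of one library: the chi-square per degree of freedom of each pair lay between 2.32 and 61.28.

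Libraries were grouped by extract and dose as the labels give them, which made 25 groups: 16 of 3 libraries, 3 of 2 libraries and 6 of 1 library. Nothing in the sources says whether the libraries of a group came from cultures grown and treated separately, so p-values measure only the spread between these libraries. The replicate numbers do not say that samples with the same number belong together. The 54 libraries of the 19 replicated groups were fitted together in edgeR 4.0.16 under R 4.3.3, with limma 3.58.1 for the gene list tests. The 17851 genes that passed edgeR's default expression filter were scaled by the trimmed mean of M values and tested with the quasi-likelihood F test, which had 35 residual degrees of freedom and 6.3 prior degrees of freedom; the trended dispersion had a median of 0.00396. Adjusted p-values of genes are Benjamini-Hochberg values over all genes tested in a comparison, and a gene passed at 0.05. Those of gene lists are Benjamini-Hochberg values over the 30 lists tested in a comparison. The standard error given with a log2 fold change is its absolute size divided by the square root of the F statistic. A prior count of 2 was used for log2 CPM, from which the fold changes of the groups of 1 library were taken. Levels are CPM, counts scaled to library size, with the SD between libraries. Each treated group was compared with the vehicle. The high-dose groups of the 2 decoctions were compared with each other, as were those of Longan Arillus and Zizyphi Semen, because each pair shared a dose and a library set. Each high and medium dose was also compared with the low dose of the same extract, which lay in the same library set.

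The genes to be named, the gene lists, the tests and the first alternatives were fixed before the data were examined. In each high-dose group the named genes were the 8 largest rises and the 8 largest falls (5 each way between extracts) among genes with a symbol that passed the threshold, reached 5 CPM in either group and had every treated library beyond every vehicle library. Up to 4 members with the lowest adjusted p were added from each list that passed its own test, and HMOX1, HMGCS1, CDKN1A, CYP1A1, MKI67 and TXNIP were followed in every group. The 30 lists covered stress responses, metabolism, cell division, cytokines and interferon, matrix, and markers of other cell types, and were tested with camera at a preset correlation between genes of 0.01 and again with a correlation estimated from the data. Where a list's count of genes is given once, the count adjusted over the list alone was the same. The groups of 1 library allow no test. In them a gene was counted when it lay at least 2-fold from the vehicle mean, outside the range of the vehicle libraries, and reached 10 CPM in either, and each list's median was placed among the medians of 10000 random lists drawn from 20 expression bins.

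The model was tested on simulated data made from these libraries. With 100 genes changed 1.5-fold and 100 changed 2-fold, the test recovered 74 and 96 of them in a 3-library group, with 8 false among 178 calls, and 81 and 90 in a 2-library group, with 13 false among 184 calls. A simulated group without change gave 0 calls. The simulated libraries shared a common mean profile and the trended dispersion. They held no length or GC trend, no deviating library and no difference between library sets, so these counts do not measure false calls from such sources. Alternatives, one at a time, were DESeq2's size factors in edgeR, DESeq2 1.42.0 itself, no expression filter, a fit of only the libraries compared, a block for the replicate number, leaving out each library in turn, the low dose as reference for the high dose, and for single libraries a minimum of 1 CPM and a prior count of 0.5. A correction for transcript length and GC content, fitted per library with splines of 4 degrees of freedom for each on genes with a mean log2 CPM above 3 and applied to the 99.2% of tested genes with a known length, thinning of all libraries to the smallest total, the comparison of the medium with the low dose, and leaving out libraries from the comparison of the high with the low dose were added after the data had been seen. The tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 and drawn with matplotlib 3.10.9. Wortmannin, a positive control in the series' design text, was not analysed here. Some genes share reads with related, overlapping or antisense genes, so the values of RGPD5, SMG1P1, KRTAP2-3, TUBA1B-AS1, PITX1-AS1, HSPA1A, ZBED6, TCAF1P1, TCAF2 and the MT1 family depend on how the counting step assigned those reads.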

Results

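The study asked which genes in SW1783 astrocytoma cells change when the cells are exposed for 24 h to extracts of herbal medicines. Yijin-tang and Soshiho-tang are decoctions of several herbs, given as water extracts at 500, 100 and 20 µg/mL, with 3 libraries per dose for Yijin-tang and 2 for Soshiho-tang. The single herbs were ethanol extracts. Liriopis seu Ophiopogonis Tuber, Longan Arillus and Zizyphi Semen were given at 500, 100 and 20 µg/mL and Schisandrae Fructus at 310, 62 and 12.4 µg/mL, with 3 libraries per dose. Polygalae Radix at 30, 6 and 1.2 µg/mL and Aucklandiae Radix at 160, 32 and 6.4 µg/mL had 1 library per dose. The vehicle group had 3 libraries. Libraries held 18.73 to 35.52 M counts, so for genes near 5 CPM (counts scaled to library size) counting error made up a larger part of the spread between libraries than for abundant genes.

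Every replicated group differed from the vehicle in many genes, from 193 at the low dose of Schisandrae Fructus to 8943 at its high dose, and most differences were small. EGR1, an immediate early transcription factor, was lower than in the vehicle (162 ± 17 CPM) at all 3 doses of Yijin-tang. Its log2 fold changes were -1.41 at the high, -1.61 at the medium and -1.51 at the low dose, and the difference between high and low dose did not pass (0.09 ± 0.26, adjusted p = 0.919). Changes of this kind, present at the lowest dose and no larger at the highest, went with the vehicle as reference. Low-dose groups differed from the vehicle in 193 to 3297 genes. They differed from each other in a median of 1 gene in 12 pairs from different library sets (range 0 to 62) and in 0 to 21 genes in 3 pairs from the same set. The vehicle libraries formed a library set of their own, so the effect of an extract at its low dose and the difference between library sets cannot be told apart. For this reason the high-dose groups were also compared with the low dose of the same extract. Values and calls below are against the vehicle unless the low dose is named. Some of the calls of lists and named genes that did not pass against the low dose are given for each extract, and others are not listed. Over all extracts 109 values of named genes lost the threshold with the low dose as reference. Effects that passed in one extract and not in another were not tested for a difference unless stated.

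**Figure D1:**
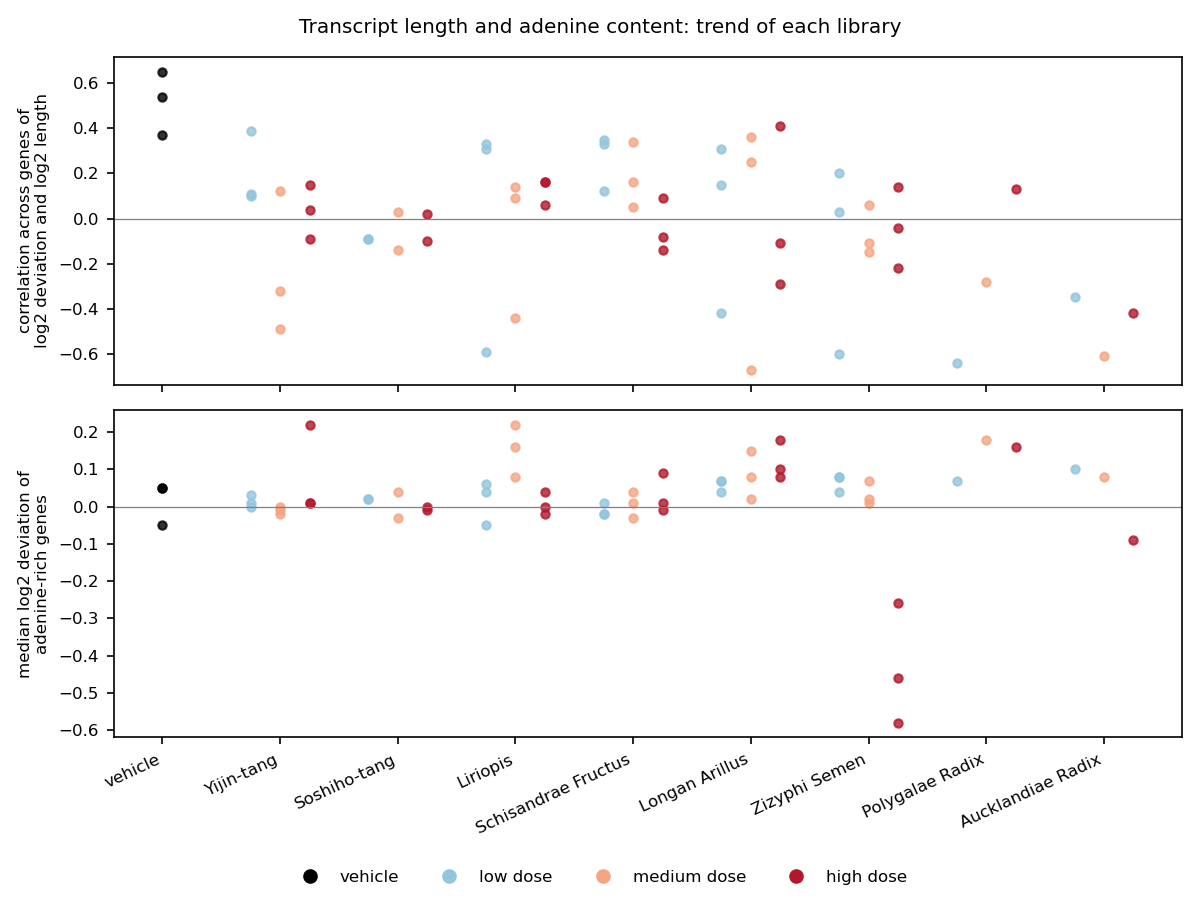
Trend of each library with transcript length (upper panel, correlation across genes between the log2 deviation from the mean of the group means and log2 length) and in adenine-rich genes (lower panel, median log2 deviation of genes with at least 36% adenine); each point is a library, coloured by dose. The vehicle libraries have length correlations of 0.37 to 0.65, and the high-dose libraries of Zizyphi Semen have adenine-rich medians of -0.58 to -0.26.

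**Figure D2:**
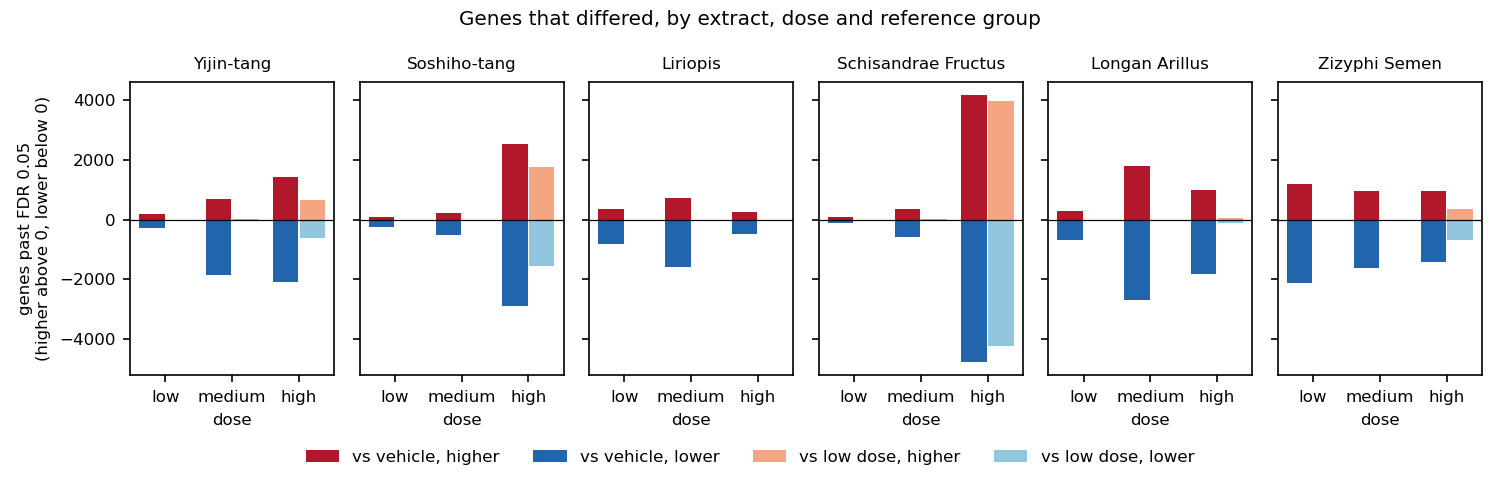
Genes past an adjusted p of 0.05 (vertical axis, higher genes above 0 and lower genes below 0) at each dose of the 6 replicated extracts, against the vehicle (dark bars) and against the low dose of the same extract (light bars). Schisandrae Fructus had 8943 genes at the high dose against the vehicle and 8195 against its low dose, while Liriopis seu Ophiopogonis Tuber had 730 and 0.

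The balance of rises and falls against the vehicle depended on the setting. Without the low-count filter rises outnumbered falls at the high doses of Yijin-tang (1674 and 1612), Soshiho-tang (2741 and 2362) and Schisandrae Fructus (4548 and 4042) and at the medium dose of Liriopis seu Ophiopogonis Tuber (1403 and 1395). Leaving out 1 library turned the balance to more rises in some other fits. These were the high doses of Soshiho-tang without its replicate 2 (1791 and 1702), of Liriopis seu Ophiopogonis Tuber without vehicle replicates 2 (33 and 30) or 3 (52 and 35) and of Zizyphi Semen without its replicates 1 (1053 and 981) or 3 (674 and 605). At the medium dose they were Schisandrae Fructus without vehicle replicate 3 (121 and 89) or its replicate 1 (337 and 190) and Zizyphi Semen without its replicates 1 (868 and 702) or 3 (606 and 463). At the low dose they were Yijin-tang without vehicle replicate 3 (39 and 33) or its replicates 2 (59 and 51) or 3 (54 and 47) and Liriopis seu Ophiopogonis Tuber without vehicle replicate 3 (44 and 36). The low doses of Schisandrae Fructus without its replicates 1 (69 and 21) or 3 (29 and 15), Longan Arillus without its replicate 3 (24 and 16) and Zizyphi Semen without its replicate 1 (573 and 409) did so too. So did the low dose of Schisandrae Fructus with DESeq2's size factors (84 and 76) and of Liriopis seu Ophiopogonis Tuber in a fit of only the libraries compared (4 and 3). In the comparison of the 2 decoctions the length and GC correction turned it to more falls (2180 and 2555).

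Yijin-tang at 500 µg/mL went with a rise of cytokine and NF-kB target transcripts (n = 3 against 3). CXCL8, a chemokine that attracts neutrophils, rose from 2.68 ± 0.507 to 54.4 ± 2.48 CPM (mean ± SD), a log2 fold change of 4.35 ± 0.11 (SE, adjusted p = 9.34e-30). CSF3, the granulocyte growth factor, rose by 4.48 ± 0.28 and IL6 by 2.7 ± 0.13, from 3.41 to 22.2 CPM. SOD2, the mitochondrial superoxide dismutase, rose from 86.9 to 315 CPM and the adhesion molecule ICAM1 from 42.2 to 157. Of the 24 measured members of the NF-kB and cytokine list 23 rose (23 adjusted over the list alone), with a median log2 fold change of 1.71 (camera adjusted p = 3.51e-67, and 4.01e-15 with an estimated correlation). BIRC3 (2.21 ± 0.09), IER3 (2.17 ± 0.16) and IL32 (1.92 ± 0.12) were the other large rises. The list's count against the low dose was 23 of 24 as well, with a median of 1.60, and CXCL8 was higher by 3.82 ± 0.10.

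Outside the cytokine genes, TXNIP, an arrestin-like protein that limits glucose uptake, rose at the high dose of Yijin-tang from 10.3 ± 0.579 to 49 ± 3.7 CPM (log2 fold change 2.25 ± 0.08, adjusted p = 1.01e-25), and its relative ARRDC4 by 1.00 ± 0.09. These 2 belong to the MondoA sugar-response list, in which 3 of 5 members rose (3 adjusted over the list alone; median 0.15, adjusted p = 0.000259, and 0.00579 with an estimated correlation). Of 24 interferon-response genes 16 rose (19 adjusted over the list alone, median 0.51, adjusted p = 2.29e-10, and 0.0359 with an estimated correlation), among them IFI6 by 1.00 ± 0.17, MX1 by 0.93 ± 0.18 and IFIT3 by 0.54 ± 0.10. Cholesterol genes went the other way: 9 of 24 fell (10 adjusted over the list alone, adjusted p = 0.000272, and 0.0284 with an estimated correlation), with HMGCS1 at -0.45 ± 0.05 and LSS at -0.41 ± 0.04. Of 8 glial and neural stem genes 4 fell (5 adjusted over the list alone, adjusted p = 0.000259, and 0.0359 with an estimated correlation), including the transcription factor SOX9 (-0.60 ± 0.07) and the glutamate transporter SLC1A3 (-0.54 ± 0.08). With the low dose as reference 9 cholesterol genes fell (12 adjusted over the list alone, adjusted p = 0.000218) and 12 interferon-response genes rose (22 adjusted over the list alone, adjusted p = 0.0059), and the MondoA list passed (adjusted p = 7.53e-05, all with an estimated correlation). The glial and neural stem list lost its call there (3 of 8 down, 4 adjusted over the list alone, adjusted p = 0.00202, and adjusted p = 0.0669 with an estimated correlation), with SOX9 at -0.38 and SLC1A3 at -0.34. Apart from EGR1, described above, the largest falls with a call in each fit that left out 1 library were LGR6 (-1.54 ± 0.18, adjusted p = 9.98e-09), LONRF2 (-1.15 ± 0.18), PADI2 (-1.11 ± 0.16), FAM13B (-1.05 ± 0.08) and TENM4 (-1.04 ± 0.17).

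Smaller shifts at this dose passed the list test with the preset correlation and not with the estimated one. Of 21 extracellular matrix genes 12 fell (13 adjusted over the list alone; adjusted p = 6.22e-07, and adjusted p = 0.124 with an estimated correlation), with COL1A2 at -0.36 ± 0.04 and COL5A1 at -0.42. Of 28 mitosis genes 10 rose (10 adjusted over the list alone; adjusted p = 0.000579, and adjusted p = 0.106 with an estimated correlation), with AURKB at 0.39 and HMMR at 0.34. Of 14 cytosolic heat shock genes 4 fell (4 adjusted over the list alone; adjusted p = 0.143 with an estimated correlation), such as HSPA8 (-0.37). Of 25 NRF2 targets 6 rose (6 adjusted over the list alone; adjusted p = 0.211 with an estimated correlation), such as AKR1C1 (0.61). Of 23 ATF4 targets 6 rose and 1 fell, the same counts as adjusted over the list alone (adjusted p = 0.252 with an estimated correlation), with DDIT4 at 0.65. Of 11 fatty acid synthesis genes 1 rose and 6 fell (1 and 8 adjusted over the list alone; adjusted p = 0.411 with an estimated correlation). Against the low dose the matrix (adjusted p = 0.063), heat shock (0.35), NRF2 (0.051), ATF4 (0.467) and fatty acid lists (0.063) did not pass with the preset correlation either, nor did AURKB as a gene (0.21, adjusted p = 0.0819). The mitosis list passed there with both (6 of 28 up, 9 adjusted over the list alone, adjusted p = 0.00567 with an estimated correlation). CDKN1A (-0.01) and CYP1A1 (0.07) did not pass. Nor did HMOX1 (0.13, but 0.20 with a call without vehicle replicate 1) and MKI67 (-0.34, but with a call in a fit of only the libraries compared and, at -0.30, without the low-count filter).

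In edgeR's test 1431 genes rose and 2095 fell at the high dose of Yijin-tang (3526, of which 164 rose and 67 fell at least 2-fold), and 644 rose and 605 fell against the low dose. The first count was 2284 without vehicle replicate 3. Falls outnumbered rises against the low dose after the length and GC correction (872 up and 979 down) and without high-dose replicate 1 (505 up and 517 down). At 100 µg/mL 687 genes rose and 1849 fell, and the cytokine list kept its direction at a smaller size, with 15 of 24 members up (17 adjusted over the list alone, median 0.43, adjusted p = 2.11e-06 with an estimated correlation) and CXCL8 at 1.48. Between 100 and 20 µg/mL 4 genes passed, all higher at 100 µg/mL: CXCL8 (0.95 ± 0.12), IL11 (0.51 ± 0.06), ICAM1 (0.31 ± 0.06) and SOD2 (0.24 ± 0.05); these 4 were chosen after their values were seen. At 20 µg/mL 179 genes rose and 288 fell, with 4 of 24 cytokine genes up (6 adjusted over the list alone, median 0.17, adjusted p = 0.0418 with an estimated correlation). The medium-dose count of 2536 was 1013 without vehicle replicate 2, 538 without vehicle replicate 3, 645 without its own replicate 1 and 1300 without its own replicate 2, and 1249 after the length and GC correction. The low-dose count of 467 was 102 and 72 without vehicle replicates 2 and 3 and 146, 110 and 101 without its own replicates 1, 2 and 3.

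**Figure D3:**
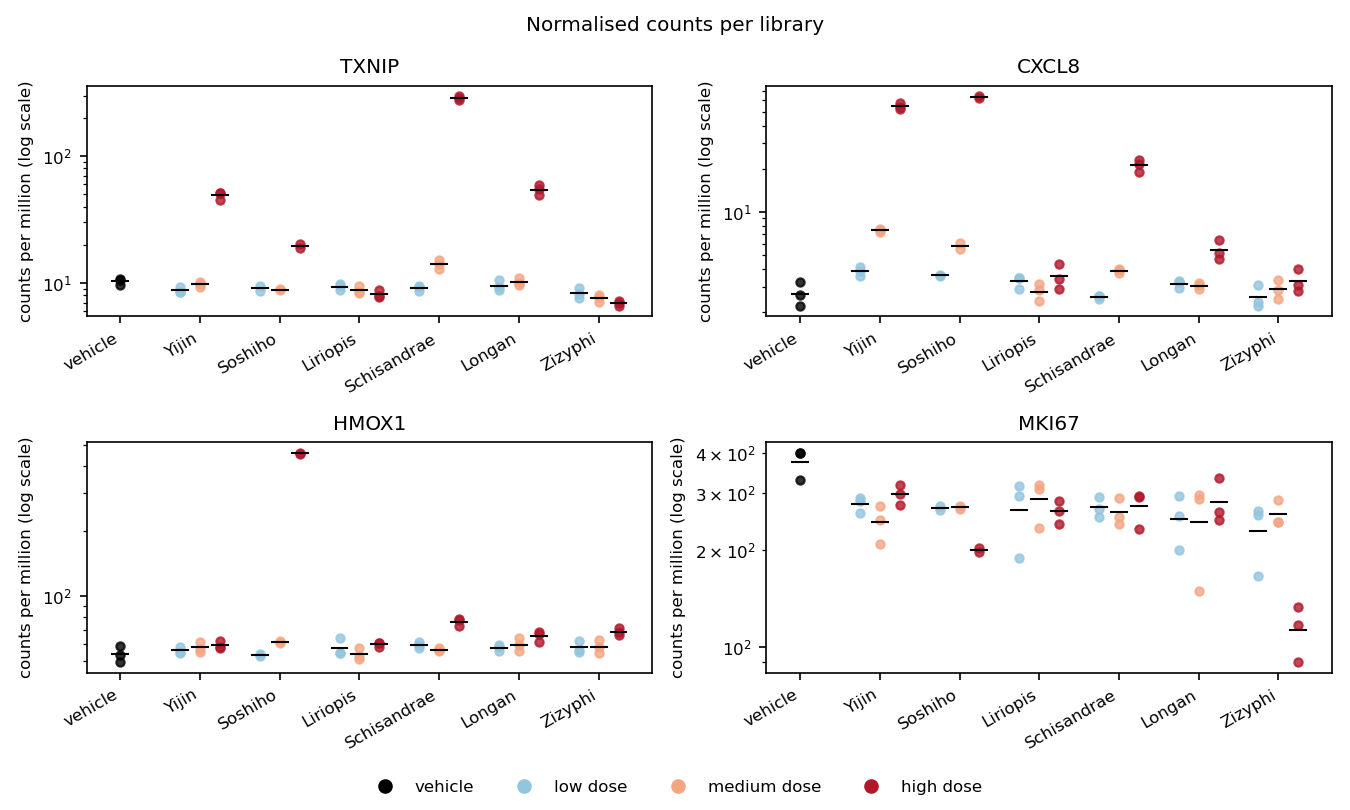
CPM (log axis) of TXNIP, CXCL8, HMOX1 and MKI67 in each library of the vehicle group and the 6 replicated extracts; each point is a library, coloured by dose, and short lines are group means. TXNIP stands at 10.3 in the vehicle and at 49, 287 and 54.2 at the high doses of Yijin-tang, Schisandrae Fructus and Longan Arillus, and HMOX1 at 54 in the vehicle and 456 at the high dose of Soshiho-tang.

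Soshiho-tang at 500 µg/mL (n = 2 against 3) combined a cytokine rise with stress responses. CXCL8 rose from 2.68 to 63.1 CPM (log2 fold change 4.56 ± 0.12, adjusted p = 3.98e-30), CXCL2 by 4.77 ± 0.24 and CXCL3 by 4.76 ± 0.29. HMOX1, which breaks down haem and is a standard NRF2 target, rose from 54 ± 4.71 to 456 ± 3.34 CPM (3.08 ± 0.07, adjusted p = 6.5e-33); its log2 fold changes of 0.18 at 100 and -0.01 at 20 µg/mL did not pass. GDF15, a stress-induced cytokine, rose by 3.30 ± 0.12, the pseudokinase TRIB3 by 2.67 ± 0.08 and the glutathione-degrading enzyme CHAC1 by 2.59 ± 0.10. Of 23 ATF4 amino acid response genes 20 rose (21 adjusted over the list alone, median 1.18, adjusted p = 3.52e-37, and 1.5e-08 with an estimated correlation), SESN2 by 2.20 ± 0.06 and ATF4 itself by 1.64 ± 0.06. Of 24 NF-kB and cytokine genes 22 rose (23 adjusted over the list alone, median 1.5, adjusted p = 7.59e-11 with an estimated correlation), and of 25 NRF2 targets 18 rose (19, median 0.36, adjusted p = 0.000287), including FTH1 (1.20), GCLC (0.85) and TXNRD1 (0.79).

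Sterol and fatty acid genes rose at the same dose of Soshiho-tang. Of 24 cholesterol genes 17 rose (17 adjusted over the list alone, median 0.36, adjusted p = 8.04e-06 with an estimated correlation), INSIG1 by 1.24 ± 0.05. Of 11 fatty acid synthesis genes 9 rose and 1 fell (median 0.38, adjusted p = 0.031 with an estimated correlation), with SREBF1 at 1.42 ± 0.08 and SCD at 1.40 ± 0.10. Of 18 immediate early genes 12 rose and 3 fell (12 and 4 adjusted over the list alone, adjusted p = 0.00293 with an estimated correlation), with ATF3 at 2.44 ± 0.14 and KLF4 at 1.60. Matrix genes fell: 17 of 21 (median -0.54, adjusted p = 0.00393 with an estimated correlation), COL1A2 from 1740 to 614 CPM, COL1A1 by -1.41 ± 0.05 and COL5A1 by -1.58 ± 0.07 on the log2 scale. Of 17 hypoxia targets 12 fell and 4 rose (13 and 4 adjusted over the list alone, adjusted p = 0.00293 with an estimated correlation), BNIP3 by -0.80 and P4HA1 by -0.75. Of 28 mitosis genes 18 fell and 1 rose (21 and 2, adjusted p = 0.01 with an estimated correlation), KIF20A by -0.69. MKI67 stood at -0.91 ± 0.21 (adjusted p = 0.000646), but at -0.43 ± 0.22 against the low dose, which did not pass (adjusted p = 0.194). The cell cycle inhibitor CDKN1A rose by 0.76 ± 0.09 and TXNIP by 0.92 ± 0.09. Among the largest falls were VAV3 (-2.72 ± 0.14), LGR6 (-2.36 ± 0.22), PADI2 (-2.05 ± 0.20) and the transcriptional regulator ID2 (-2.01 ± 0.11). The ATF4, NF-kB, NRF2, cholesterol, fatty acid, immediate early, matrix, hypoxia and mitosis lists passed against the low dose too, with both correlations. The medians there were -0.26 for matrix and -0.27 for hypoxia genes.

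Targets of the aryl hydrocarbon receptor fell at every dose of Soshiho-tang. CYP1B1, a cytochrome P450 enzyme, was at 34 CPM at the high dose against 122 in the vehicle, and its log2 fold change was -1.85 ± 0.08 at 500, -1.41 at 100 and -0.94 at 20 µg/mL, all past the threshold. AHRR, the repressor of the receptor, stood at -1.39 ± 0.09, -1.29 and -0.83, and TIPARP at -0.66, -1.01 and -0.69. Of the 6 measured list members 1 rose and 5 fell at the high dose (median -1.39, adjusted p = 0.0016 with an estimated correlation). At the medium dose 4 fell (5 adjusted over the list alone, median -1.11, adjusted p = 3.98e-08) and at the low dose 3 fell (median -0.52, adjusted p = 2.42e-05, both with an estimated correlation). CYP1B1 differed from the low dose by -0.91 ± 0.09 and TIPARP did not differ (0.03, adjusted p = 0.899), and the list did not pass (adjusted p = 0.0525). Between 100 and 20 µg/mL 2 genes passed, CYP1B1 (-0.47 ± 0.08) and ALDH1A3 (-0.28 ± 0.05), which were chosen after their values were seen.

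At the high dose of Soshiho-tang 2526 genes rose and 2887 fell (5413, of which 299 rose and 374 fell at least 2-fold), and against its low dose 1770 rose and 1546 fell (1978 and 2225 after the length and GC correction). The list calls of p53 targets (7 up and 5 down of 19, 8 and 5 adjusted over the list alone, adjusted p = 0.0591) and DNA replication (3 up and 13 down of 26, 3 and 14 adjusted over the list alone, adjusted p = 0.201) were lost with an estimated correlation. So were those of glycolysis (9 down of 16, LDHA at -0.68, adjusted p = 0.125) and of lysosome and autophagy (5 up and 2 down of 20, SQSTM1 at 1.29, adjusted p = 0.218). When compared with the low dose, p53 targets (adjusted p = 0.0268) and glycolysis (0.0418) passed with the estimated correlation, and DNA replication (0.057) and lysosome and autophagy (0.0948) did not. The high-dose count was 3493 without its own replicate 2, and the count against the low dose, 3316, was 2164 without low-dose replicate 3. At 100 µg/mL 226 genes rose and 523 fell, and at 20 µg/mL 95 rose and 246 fell. The medium-dose count of 749 was 297 and 243 without vehicle replicates 2 and 3 and 92 and 185 without its own replicates 2 and 3. The low-dose count of 341 was 709, 73 and 46 without vehicle replicates 1, 2 and 3 and 31 and 36 without its own replicates 2 and 3.

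Between the high and the low dose of Liriopis seu Ophiopogonis Tuber edgeR called 0 genes (463 had an unadjusted p under 0.05, and 1 gene passed after the length and GC correction) and 2 gene lists passed with both correlations (n = 3 per group). The nuclear non-coding RNA MALAT1 was higher than in the vehicle at 500 µg/mL (1360 against 827 CPM, log2 fold change 0.72 ± 0.14, adjusted p = 0.00317) and at the medium (0.96) and low dose (0.77), and high and low dose differed by -0.04. BCL2L11, which promotes apoptosis, fell by 0.67 ± 0.11 (adjusted p = 0.000624), the cytokine LIF rose by 0.46 ± 0.08 and the transcription factor CEBPB by 0.50 ± 0.10, and the heat shock gene HSPA1A fell by 0.34 ± 0.05. Of the 16 genes with the largest changes 14 lost their call with at least 1 of the libraries left out. EGR1 stood at -1.16 ± 0.26 (adjusted p = 0.00988) and lost its call without vehicle replicate 2 (-1.12), vehicle replicate 3 (-1.11), its own replicate 2 (-1.08) or its own replicate 3 (-1.12). Of 30 lists 8 passed against the vehicle with the preset correlation, and each of these calls was lost with the estimated one. In the list with the lowest p, 7 of 21 matrix genes fell (16 adjusted over the list alone, median -0.19, adjusted p = 5.19e-10, and adjusted p = 0.115 with an estimated correlation), and against the low dose it did not pass (adjusted p = 0.936).

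At the medium dose of Liriopis seu Ophiopogonis Tuber edgeR called 0 genes against the low dose (1 after the length and GC correction), and 1300 had an unadjusted p under 0.05. The 2 lists past the threshold between high and low dose moved little. Of 18 endoplasmic reticulum chaperone genes 0 passed over all genes and 2 rose adjusted over the list alone, with a median of 0.06 (adjusted p = 0.00104 with an estimated correlation). The 6 aryl hydrocarbon receptor genes had a median of 0.13 (adjusted p = 0.0258 with an estimated correlation). Against the vehicle 254 genes rose and 476 fell at 500 µg/mL, 724 and 1588 at 100 µg/mL and 360 and 817 at 20 µg/mL. The share that rose at the high dose, 34.8%, was 45% with DESeq2's size factors. The high-dose count of 730 was 63 and 87 without vehicle replicates 2 and 3 and 292, 148 and 61 without its own replicates 1, 2 and 3. The medium-dose count of 2312 was 656 and 402 without vehicle replicates 2 and 3 and 321 without its own replicate 2. The low-dose count of 1177 was 116 and 80 without vehicle replicates 2 and 3, 51 and 558 without its own replicates 2 and 3, 629 after the length and GC correction and 7 in a fit of only the libraries compared.

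Schisandrae Fructus at 310 µg/mL gave the most genes past the threshold of the replicated groups (n = 3 against 3). TXNIP rose from 10.3 ± 0.579 to 287 ± 9.97 CPM, a log2 fold change of 4.79 ± 0.08 (adjusted p = 2.24e-38), and its relative ARRDC4 from 5.76 to 29.4 (2.35 ± 0.09). All 5 MondoA sugar-response genes rose (5 adjusted over the list alone, median 1.83, adjusted p = 0.00055 with an estimated correlation), HK2 among them by 0.52, and all 5 rose against the low dose (median 2.15). Other large rises were the keratin-associated gene KRTAP2-3 (3.78 ± 0.15), CXCL8 (2.99 ± 0.12, from 2.68 to 21.2 CPM), thrombomodulin THBD (2.79 ± 0.06), the lipase inhibitor ANGPTL4 (2.37 ± 0.10) and IL1B (2.28 ± 0.10). The largest falls were LGR6 (-3.44 ± 0.21), the integrin ITGB8 (-3.25 ± 0.11, from 48.8 to 5.12 CPM), the serotonin receptor HTR2A (-2.91 ± 0.16), VAV3 (-2.79 ± 0.12) and NDST3 (-2.50 ± 0.16).

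Amino acid response genes rose and DNA replication genes fell at the high dose of Schisandrae Fructus. Of 23 ATF4 targets 21 rose and 1 fell (22 and 1 adjusted over the list alone, median 0.61, adjusted p = 2.66e-12, and 0.00055 with an estimated correlation), TRIB3 by 1.39, ASNS by 1.16 and SESN2 by 1.07. Of 26 DNA replication genes 22 fell (22 down and 1 up adjusted over the list alone, median -0.31, adjusted p = 0.0286 with an estimated correlation), MCM3 by -0.90 ± 0.04 and UHRF1 by -0.86. Of 28 mitosis genes 18 rose and 4 fell (median 0.21, adjusted p = 0.00014, and adjusted p = 0.06 with an estimated correlation), AURKB by 0.73 and KIF2C by 0.43. Against the low dose 20 rose and 1 fell (21 and 1 adjusted over the list alone, adjusted p = 0.0142 with an estimated correlation). MKI67 stood at -0.46 ± 0.18 (adjusted p = 0.0323) and lost its call without vehicle replicate 2 (-0.42), vehicle replicate 3 (-0.41) or its own replicate 3 (-0.36) and after the length and GC correction (-0.19), and stood at 0.01 against the low dose. Of 24 NF-kB and cytokine genes 15 rose and 2 fell (median 0.59, adjusted p = 0.00381 with an estimated correlation). Of 7 neuronal markers 5 fell and 1 rose (median -1.13, adjusted p = 0.0134 with an estimated correlation), MAP2 by -2.05 and NEFL by -1.95. Against the low dose the ATF4 (adjusted p = 0.00118), DNA replication (0.02), NF-kB (0.00744) and neuronal lists (0.00803) passed with the estimated correlation as well.

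Several groups at this dose passed only with the preset correlation. Of 24 interferon-response genes 15 fell and 2 rose (median -0.58, adjusted p = 0.00152, and adjusted p = 0.326 with an estimated correlation), IFIT1 by -1.55 ± 0.13. Of 25 NRF2 targets 15 rose and 2 fell (adjusted p = 0.0746 with an estimated correlation), AKR1C1 by 1.82 ± 0.07 and SRXN1 by 0.65. Of 18 endoplasmic reticulum chaperones 9 rose and 3 fell (adjusted p = 0.121 with an estimated correlation), HSPA5 from 3100 to 5430 CPM (0.81 ± 0.04); against the low dose 12 rose and 1 fell (median 0.25, adjusted p = 0.0153 with an estimated correlation). Of 8 glial and neural stem genes 5 fell (adjusted p = 0.121 with an estimated correlation), SLC1A3 by -1.42 ± 0.08. The calls of p53 targets (9 up and 3 down of 19, TNFRSF10B at 0.73, adjusted p = 0.142) and immediate early genes (8 up and 6 down of 18, DUSP1 at 1.17, adjusted p = 0.347) were lost with an estimated correlation. So was that of fatty acid synthesis (1 up and 7 down of 11, adjusted p = 0.458), which did not pass against the low dose with the preset correlation either (adjusted p = 0.159). HMOX1 (0.50), HMGCS1 (-0.39) and CYP1A1 (0.90, adjusted p = 0.00051, but 0.17 with adjusted p = 0.502 against the low dose) passed and CDKN1A (-0.06, adjusted p = 0.593) did not.

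At the high dose of Schisandrae Fructus 4174 genes rose and 4769 fell (639 and 725 at least 2-fold), and against the low dose 3976 rose and 4219 fell. At 62 µg/mL 366 rose and 596 fell, and at 12.4 µg/mL 84 rose and 109 fell. Between 62 and 12.4 µg/mL 5 genes were higher and 2 lower, and after the length and GC correction 8 were higher and 9 lower. Among them TXNIP (0.62 ± 0.08, adjusted p = 3.18e-05), ALDH1A3 (0.27 ± 0.04), RGMB (0.23 ± 0.04) and CPM (0.27 ± 0.06) were higher and LIPG (-0.46 ± 0.06) and FAM13B (-0.41 ± 0.08) lower. Except for TXNIP these were chosen after their values were seen. The MondoA list moved with TXNIP between these doses (1 of 5 up, 3 adjusted over the list alone, median 0.26, adjusted p = 0.000377 with an estimated correlation). The medium-dose count of 962 was 309 and 210 without vehicle replicates 2 and 3 and 527, 403 and 299 without its own replicates 1, 2 and 3. The low-dose count of 193 was 300, 43 and 29 without vehicle replicates 1, 2 and 3 and 90, 48 and 44 without its own replicates 1, 2 and 3.

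At 500 µg/mL of Longan Arillus TXNIP rose and endoplasmic reticulum chaperones fell (n = 3 against 3). TXNIP went from 10.3 ± 0.579 to 54.2 ± 4.88 CPM (log2 fold change 2.39 ± 0.08, adjusted p = 3.11e-26) and ARRDC4 from 5.76 to 11.7 (1.02 ± 0.09). The differences from the low dose were 2.51 ± 0.07 and 0.95 ± 0.09. HSPA5, the main chaperone of the endoplasmic reticulum, fell from 3100 to 2260 CPM (-0.45 ± 0.04, adjusted p = 9.12e-11). HERPUD1 fell by 0.53 ± 0.05, PDIA4 by 0.26 and HYOU1 by 0.24. Of 18 chaperone genes 13 fell (14 adjusted over the list alone, median -0.25, adjusted p = 1.46e-14, and 2.05e-05 with an estimated correlation), and 8 fell against the low dose (9 adjusted over the list alone). Of 17 hypoxia targets 10 fell and 1 rose (12 and 1 adjusted over the list alone, median -0.25, adjusted p = 0.000437 with an estimated correlation), BNIP3 by -0.54 and P4HA1 by -0.38. CXCL8 rose by 1.02 ± 0.14 (2.68 to 5.39 CPM) and LIF by 0.60, and 7 of 24 NF-kB and cytokine genes rose (9 adjusted over the list alone, median 0.27, adjusted p = 0.00267 with an estimated correlation).

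At the high dose of Longan Arillus, of 6 aryl hydrocarbon receptor genes 3 rose (4 adjusted over the list alone, median 0.30, adjusted p = 0.00267 with an estimated correlation), NQO1 by 0.27 and TIPARP by 0.32; against the low dose these 2 did not pass (0.21, adjusted p = 0.0518, and 0.29, adjusted p = 0.0594). CYP1A1 stood at 0.86 ± 0.22 and lost its call without vehicle replicate 1 (0.66), its own replicate 2 (0.68) or its own replicate 3 (0.70), and against the low dose (0.42, adjusted p = 0.465). Of 5 MondoA genes 2 rose and 1 fell (3 and 1 adjusted over the list alone, adjusted p = 0.00365 with an estimated correlation). HTR2A fell by 0.90 ± 0.13 and POMK by 0.91 ± 0.18, without a difference from the low dose that passed. The other 10 lists past the threshold passed only with the preset correlation. Among them were matrix genes (11 of 21 down), NRF2 targets (7 of 25 up, 12 adjusted over the list alone) and mitosis genes (8 of 28 up, 13 adjusted over the list alone), each at adjusted p = 0.0813 with an estimated correlation. Glycolysis (6 of 16 down, 8 adjusted over the list alone) and the epithelial markers (2 of 7 up) were at adjusted p = 0.094 with an estimated correlation. The chaperone, hypoxia, NF-kB, aryl hydrocarbon receptor and MondoA lists passed against the low dose with both correlations, and so did mitosis genes and glycolysis. The matrix genes (0 of 21 down, adjusted p = 0.382) and the epithelial markers (adjusted p = 0.374) did not pass there with the preset one. Against the low dose, 4 of 23 ATF4 targets fell (9 adjusted over the list alone, adjusted p = 0.00135 with an estimated correlation). So did 2 of 5 metallothionein and zinc genes (3 adjusted over the list alone, adjusted p = 0.0012 with an estimated correlation), MT1E standing at -0.64 ± 0.17 against the vehicle.

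At the high dose of Longan Arillus 1002 genes rose and 1837 fell (82 and 41 at least 2-fold), and 61 rose and 106 fell against the low dose. At 100 µg/mL 1794 rose and 2707 fell, with TXNIP at -0.02, and edgeR called 0 of these genes against the low dose (1022 had an unadjusted p under 0.05). At 20 µg/mL 291 rose and 674 fell. The high-dose count of 2839 was 1557 and 1280 without vehicle replicates 2 and 3 and 1829 and 1013 without its own replicates 2 and 3. Its count of 167 against the low dose was 103, 107 and 90 without high-dose replicates 1, 2 and 3 and 90, 99 and 97 without low-dose replicates 1, 2 and 3, and 360 after the length and GC correction. The medium-dose count of 4501 was 2435 without vehicle replicate 3 and 359 without its own replicate 3. It was 2892 after the length and GC correction and 0 in a fit of only the libraries compared. Medium-dose replicate 3 stood apart from the others of its group. Counted like the groups of 1 library, it had 436 genes at least 2-fold from the vehicle, and replicates 1 and 2 had 4 and 9. The low-dose count of 965 was 127 and 50 without vehicle replicates 2 and 3 and 176 and 40 without its own replicates 1 and 3.

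At 500 µg/mL of Zizyphi Semen (n = 3 against 3) the largest fall, RGPD5 (-2.61 ± 0.81, adjusted p = 0.0262), lost its call without vehicle replicates 1 (-2.43) or 2 (-2.41), its own replicates 1 (-2.51), 2 (-2.55) or 3 (-2.73), and against the low dose (-1.81, adjusted p = 0.237). CENPE, a kinesin of the mitotic spindle, fell from 60.6 ± 2.14 to 10.5 ± 4.83 CPM (log2 fold change -2.53 ± 0.13, adjusted p = 1.23e-18), and high and low dose differed by -2.45 ± 0.13. The scaffold protein AKAP9 fell by 1.86 ± 0.13 (125 to 34.4 CPM), ANKRD12 by 1.84 ± 0.16 and the Golgi protein GOLGA4 by 1.74 ± 0.12 (172 to 51.5). The proliferation marker MKI67 fell by 1.73 ± 0.19 (376 to 113), CEP290 by 1.71 ± 0.14 and GOLGB1 by 1.65 ± 0.14. CENPF fell from 277 to 90.5 CPM (-1.61 ± 0.11). MKI67 fell less against the low dose, by 1.02 ± 0.19 (adjusted p = 0.000224). AKAP9 stood there at -1.84, ANKRD12 at -2.04, GOLGA4 at -1.59, CEP290 at -1.60, GOLGB1 at -1.25 and CENPF at -1.24, all past the threshold. The spread between the 3 high-dose libraries was wide for AKAP9 (SD 17.2) and GOLGA4 (SD 19.7). Of 28 mitosis genes 14 fell and 2 rose (15 and 2 adjusted over the list alone, median -0.12, adjusted p = 3.88e-07, and 0.0137 with an estimated correlation). Compared with the low dose 7 fell (8 adjusted over the list alone, adjusted p = 0.0145 with an estimated correlation).

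Amino acid response and hypoxia genes rose at the high dose of Zizyphi Semen. Of 23 ATF4 targets 12 rose (15 adjusted over the list alone, median 0.19, adjusted p = 1.23e-11, and 0.00164 with an estimated correlation), the hormone STC2 by 0.34 ± 0.04. Of 17 hypoxia targets 7 rose (8 up and 1 down adjusted over the list alone, median 0.17, adjusted p = 0.00209 with an estimated correlation), NDRG1 by 0.45, BNIP3 by 0.29 and the glucose transporter SLC2A1 by 0.21. Compared with the low dose 8 hypoxia targets (11 adjusted over the list alone) and 4 ATF4 targets (7 adjusted over the list alone, adjusted p = 0.0195 with an estimated correlation) rose. ANGPTL4 rose from 12.8 to 27.8 CPM (1.12 ± 0.10, adjusted p = 9.11e-11; 1.42 ± 0.10 against the low dose), TUBA1B-AS1 by 1.37 ± 0.36, KRTAP2-3 by 0.88 ± 0.17 and the small heat shock gene HSPB6 by 0.77 ± 0.17. TUBA1B-AS1 (0.09, adjusted p = 0.929) and HSPB6 (0.16, adjusted p = 0.658) did not pass against the low dose. TXNIP fell by 0.59 ± 0.09 (adjusted p = 2.77e-05), with -0.27 against the low dose (adjusted p = 0.0814). Of 13 mitochondrially encoded respiratory chain genes 10 rose against the vehicle (12 adjusted over the list alone, median 0.42, adjusted p = 1.37e-07, and adjusted p = 0.176 with an estimated correlation), MT-CO3 by 0.42, and no member passed against the low dose. Calls of glycolysis (4 of 16 up, 5 adjusted over the list alone, adjusted p = 0.176) and matrix genes (8 of 21 down, 12 adjusted over the list alone, adjusted p = 0.257) were lost with an estimated correlation. So were those of heat shock (7 of 14 down, 8 adjusted over the list alone, adjusted p = 0.192) and NF-kB genes (4 of 24 up, adjusted p = 0.0879). Against the low dose glycolysis passed with both correlations (5 up, 10 adjusted over the list alone, adjusted p = 0.0307 with an estimated one), and matrix (adjusted p = 0.162) and heat shock genes (0.366) did not pass with the preset one.

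At the high dose of Zizyphi Semen 946 genes rose and 1423 fell (32 and 98 at least 2-fold), and against the low dose 360 rose and 671 fell. At 100 µg/mL 948 rose and 1627 fell, with CENPE at -0.17 (adjusted p = 0.307), and edgeR called 0 genes against the low dose (679 had an unadjusted p under 0.05). At 20 µg/mL 1180 rose and 2117 fell. The high-dose count of 2369 was 1397 and 1240 without vehicle replicates 2 and 3 and 1526 and 1279 without its own replicates 2 and 3, and its count of 1031 against the low dose was 556 without high-dose replicate 2 and 1540 after the length and GC correction. The medium-dose count of 2575 was 1229 and 850 without vehicle replicates 2 and 3 and 1570, 1541 and 1069 without its own replicates 1, 2 and 3. The low-dose count of 3297 was 2135 and 1491 without vehicle replicates 2 and 3 and 982 without its own replicate 1.

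**Figure D4:**
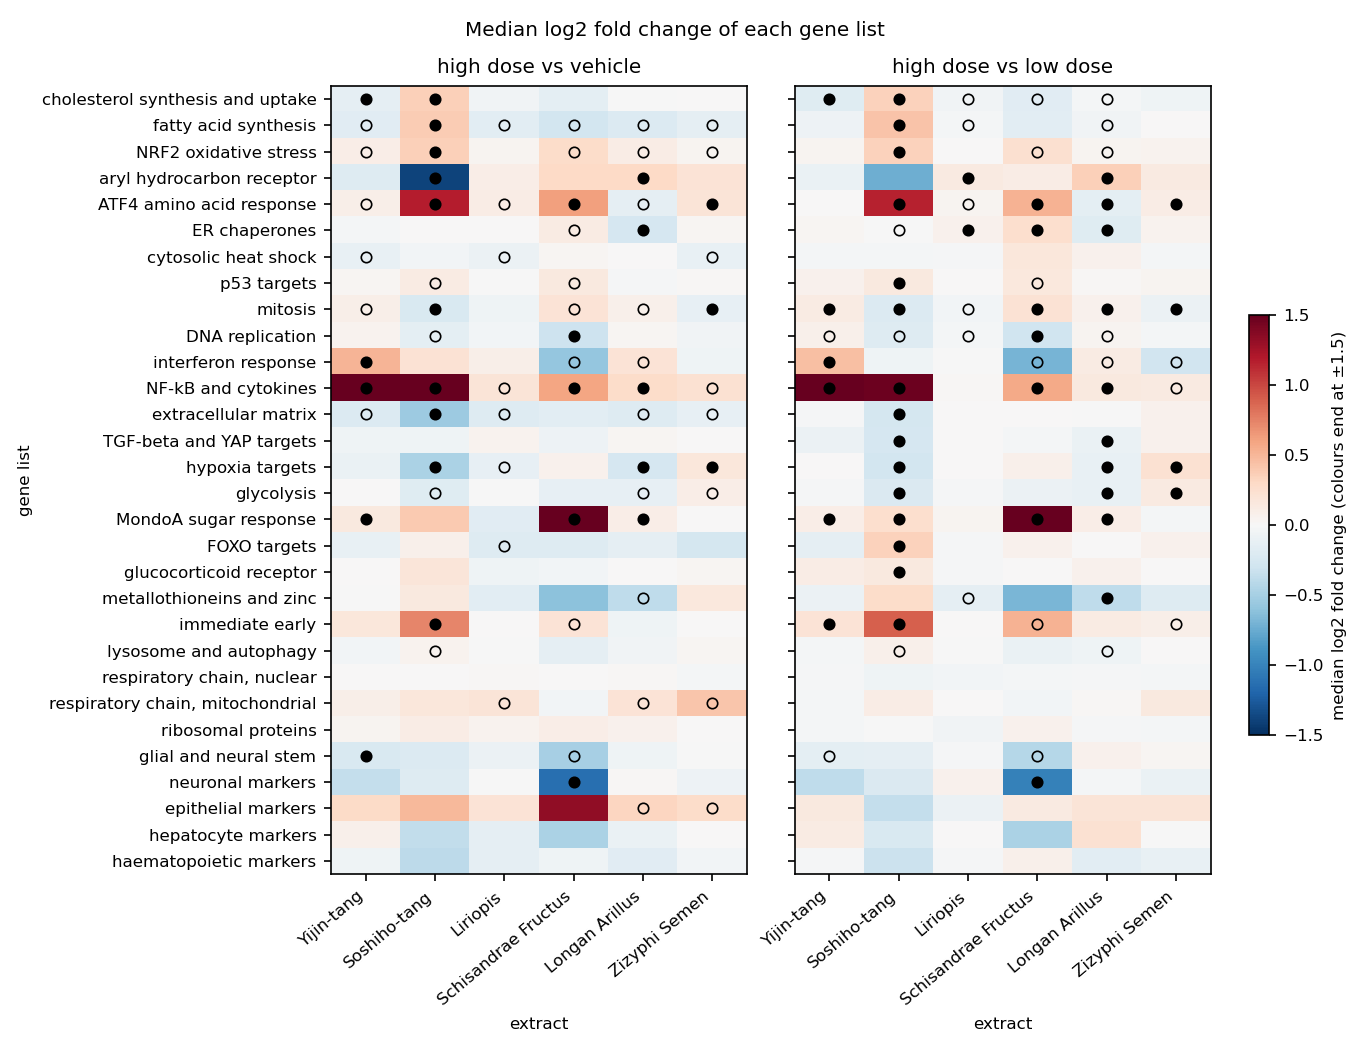
Median log2 fold change of the members of each gene list (rows) at the high dose of each extract (columns) against the vehicle (left) and against the low dose (right); circles mark an adjusted p under 0.05 in camera with the preset correlation, filled where the estimated correlation gave the same. The NF-kB and cytokine list stands at 1.71 for Yijin-tang and 1.5 for Soshiho-tang, and the MondoA list at 1.83 for Schisandrae Fructus.

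The decoctions were compared directly at 500 µg/mL (Soshiho-tang, n = 2, against Yijin-tang, n = 3). HMOX1 stood at 456 CPM in Soshiho-tang and 59.2 in Yijin-tang (log2 difference 2.95 ± 0.07), GDF15 at 28.1 and 3.14 (3.16 ± 0.12), and ADM2 (2.62 ± 0.10), TRIB3 (2.55 ± 0.08) and CHAC1 (2.50 ± 0.10) were higher in Soshiho-tang too. RASL11A (-2.45 ± 0.12), ID2 (-1.93 ± 0.11), VAV3 (-1.86 ± 0.14), SERPINB3 (-1.85 ± 0.21) and TXNIP (-1.33 ± 0.08) were lower. Of 23 ATF4 targets 20 were higher (21 adjusted over the list alone, median 1.13, adjusted p = 6.39e-09 with an estimated correlation). So were 18 of 24 cholesterol genes (20 adjusted over the list alone, median 0.54, adjusted p = 1.91e-08), 10 of 11 fatty acid synthesis genes (median 0.49, adjusted p = 0.00322) and 15 of 25 NRF2 targets (19 adjusted over the list alone, median 0.24, adjusted p = 0.000496). Lower were 20 of 28 mitosis genes (21 adjusted over the list alone, median -0.29, adjusted p = 9.2e-05) and 14 of 26 DNA replication genes (15 down and 1 up adjusted over the list alone, adjusted p = 0.0361). The same held for 11 of 21 matrix genes (adjusted p = 0.0149) and 4 of 6 aryl hydrocarbon receptor genes with 1 higher (5 and 1 adjusted over the list alone, median -1.03, adjusted p = 0.000508, all with an estimated correlation). NF-kB and cytokine genes went both ways, 7 higher and 10 lower of 24 (8 and 10 adjusted over the list alone), with a median of -0.17 and a mean of 0.02 (adjusted p = 0.255). In all 2022 genes were higher and 1896 lower (158 and 253 at least 2-fold), and the count of 3918 was 2519 and 2532 without Soshiho-tang replicates 2 and 3.

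Longan Arillus and Zizyphi Semen were compared at the same dose (n = 3 each). TXNIP was higher in Longan Arillus (54.2 against 6.91 CPM, log2 difference 2.98 ± 0.08), as were CENPE (2.55 ± 0.12), ANKRD12 (2.01 ± 0.16), AKAP9 (1.83 ± 0.13), CEP290 (1.79 ± 0.14) and MKI67 (1.32 ± 0.19). The peptide hormone APLN (-1.18 ± 0.16), ANGPTL4 (-0.94 ± 0.10), AK4 (-0.88 ± 0.07), MT1E (-0.83 ± 0.16) and ADM2 (-0.83 ± 0.12) were lower. Of 28 mitosis genes 20 were higher (23 adjusted over the list alone, median 0.21, adjusted p = 3.39e-06 with an estimated correlation). Lower were 18 of 23 ATF4 targets (20 adjusted over the list alone, median -0.34, adjusted p = 3.39e-06 with an estimated correlation) and 12 of 17 hypoxia targets (13, median -0.38, adjusted p = 1.49e-08). The same held for 13 of 16 glycolysis genes (14, median -0.27, adjusted p = 0.000919) and 12 of 18 endoplasmic reticulum chaperones (13, median -0.22, adjusted p = 1.02e-06). The interferon-response call (8 of 24 higher, 13 adjusted over the list alone, adjusted p = 1.3e-05) was lost with the estimated correlation (adjusted p = 0.134). In all 1000 genes were higher and 856 lower (79 and 12 at least 2-fold); the count of 1856 was 1019 without Zizyphi Semen replicate 2, 1035 without Longan Arillus replicate 3 and 858 in a fit of only the libraries compared.

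The differences between high and low dose use separate libraries for each extract and were correlated across the 9729 genes with at least 10 CPM; genes are not independent replicates. The 5 highest of the 15 correlations between extracts were 0.54 for Yijin-tang and Schisandrae Fructus, 0.43 for Soshiho-tang and Schisandrae Fructus, 0.43 for Schisandrae Fructus and Longan Arillus, 0.39 for Yijin-tang and Longan Arillus and 0.37 for Yijin-tang and Soshiho-tang. The other 10 lay between -0.09 and 0.25. Over all 17851 genes the same 5 pairs gave 0.23, 0.20, 0.16, 0.10 and 0.20. For Yijin-tang and Zizyphi Semen the sign depended on the genes taken, with -0.07 above 10 CPM and 0.10 over all genes. Among all 17851 genes, Yijin-tang and Schisandrae Fructus shared 409 rises past the threshold, where 143.4 would be shared by chance. They shared 501 falls, where 143 would be, while 106 genes went in opposite directions. The chance values take every gene as equally likely to pass, whatever its level, so they may be too low. No chance value was made for opposite directions, so an excess of shared calls alone does not show a common response. Yijin-tang and Soshiho-tang shared 280 rises (63.9 by chance) and 306 falls (52.4 by chance), with 101 opposite. Soshiho-tang and Schisandrae Fructus shared 930 rises (394.2 by chance) and 939 falls (365.4), with 398 opposite. More genes were shared than opposite for Yijin-tang and Longan Arillus (31 rises, 40 falls, 10 opposite) and Schisandrae Fructus and Longan Arillus (44, 75, 27). The same held for Zizyphi Semen with Soshiho-tang (116, 140, 107) and with Schisandrae Fructus (196, 231, 229). In some pairs about as many were opposite as shared. These were Yijin-tang and Zizyphi Semen with 47 rises (13 by chance), 34 falls (22.7) and 80 opposite, Soshiho-tang and Longan Arillus with 15 (6), 30 (9.2) and 48, and Longan Arillus and Zizyphi Semen with 11 (1.2), 6 (4) and 18.

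Polygalae Radix was measured in 1 library per dose, so its values carry no error of their own and were not tested. At 30 µg/mL matrix genes stood far below the vehicle. Tenascin TNC was at 30.9 against 789 ± 23.6 CPM, a log2 fold change of -4.67, with -1.57 at 6 and -0.93 at 1.2 µg/mL. COL1A2 stood at 151 against 1790 (-3.57), fibronectin FN1 at 430 against 4640 ± 321 (-3.43) and the aminopeptidase ANPEP at 106 against 1260 (-3.58). All 21 matrix genes were at least 2-fold lower, with a median of -2.22 where expression-matched random lists had -0.44. Of 16 glycolysis genes 13 were at least 2-fold lower (median -1.89, random -0.42), GAPDH at 597 against 4100 CPM and LDHA at 241 against 1840. The medians of the cholesterol (-0.92), fatty acid (-1.26), heat shock (-1), mitosis (-0.78), hypoxia (-0.85) and nuclear respiratory chain lists (-0.84) lay in the lowest 0.5% of random lists too, with MKI67 at -1.80 (-1.18 at 6 and -1.17 at 1.2 µg/mL). The same held for neuronal (-1.23), haematopoietic (-1.84) and hepatocyte markers (-2.12). Higher were GDF15 (3.37, 31.3 against 2.94 ± 0.128 CPM) and IFIT2 (3.14). In the highest 0.5% stood the medians of mitochondrially encoded respiratory chain genes (0.60, with 0.45 at 6 and 0.37 at 1.2 µg/mL in the highest 0.5% as well), p53 targets (0.60, with MDM2 at 1.12 and TP53INP1 at 1.5) and FOXO targets (0.78, with IRS2 at 1.58). At least 2-fold from the vehicle were 621 genes up and 1345 down at 30, 98 genes at 6 and 147 genes at 1.2 µg/mL, against 1 or 2 genes for each vehicle library compared with the other vehicle libraries. The vehicle libraries share a set that holds no treated library, so this background leaves out differences between sets. Low-dose libraries of the replicated extracts, counted the same way, had 1 to 84 genes. The library at 1.2 µg/mL had a length correlation of -0.64. This limit holds for the lower-dose values of single genes and lists above too.

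Aucklandiae Radix also had 1 library per dose. At 160 µg/mL HMOX1 stood at 1280 against 53.9 ± 5.09 CPM (log2 fold change 4.57, and 0.80 at 32 and 0.24 at 6.4 µg/mL), ANGPTL4 at 310 against 12.8 ± 2.26 (4.61) and THBD at 109 against 8.64 (3.64). The ferritin chain FTH1 was at 4240 against 1140 and AKR1C1 at 106 against 18.1, and the median of 25 NRF2 targets was 0.93, with 9 at least 2-fold higher. The medians of the ATF4 list (0.80), the metallothioneins (1.96), the immediate early genes (0.69), the NF-kB list (0.59) and the hypoxia list (0.51) lay in the highest 0.5% of random lists as well. SLC3A2 stood at 640 against 153 CPM and MT2A at 445 against 114. Of 28 mitosis genes 24 were at least 2-fold lower (median -1.56), MKI67 at 33.5 against 375 ± 38.2 CPM and KIF20A at 11.7 against 128, while the cell cycle inhibitor CDKN1A was at 90.2 against 21.7. The interferon (-0.68) and matrix lists (-1.19) lay in the lowest 0.5%, with COL1A1 at 1010 against 3680, and VAV3 (-4.03) and TXNIP (-2.69) were among the low genes. The mitochondrially encoded respiratory chain list lay in the highest 0.5% at 6.4 µg/mL (0.42) and not at 160 µg/mL (-0.18). At least 2-fold from the vehicle were 426 genes up and 870 down at 160, 262 genes at 32 and 38 genes at 6.4 µg/mL. CXCR5 and ZACN had the largest rises at the high dose of both single-library extracts, as 6.54 and 5.13 for Polygalae Radix, but their vehicle libraries differed widely (2.11 ± 3.65 and 1.07 ± 1.71 CPM).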

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

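The length and GC correction, thinning, the medium doses against the low dose, and leaving out libraries from the high against the low dose were chosen after the data had been seen. Of 5710 alternative values of 417 named gene results, 5188 kept their direction and their side of the threshold, 440 lost the threshold, 58 gained it and 24 changed direction. Of the values kept, 2147 came from fits with 1 library left out. Most named genes were chosen from these same libraries for large or clear changes. That choice favours a kept call, so these counts are no independent check. With the low dose as reference fewer held: 252 kept both, 109 lost the threshold, 2 gained it and 24 changed direction. The count at the high dose of Schisandrae Fructus stayed within 1.5 times of 8943 in every alternative run. With 3 libraries per group, or 2 for Soshiho-tang, leaving out 1 leaves few libraries to estimate a group's mean, and where this left small groups the remaining libraries were assumed to vary like the others. With 1 library left out, the counts ran from 2284 to 3316 at the high, 538 to 2796 at the medium and 72 to 675 at the low dose of Yijin-tang. In the same order they were 3493 to 5186, 92 to 1048 and 31 to 709 for Soshiho-tang and 61 to 1068, 321 to 2415 and 51 to 1601 for Liriopis seu Ophiopogonis Tuber. They were 7904 to 8743, 210 to 1248 and 29 to 300 for Schisandrae Fructus and 1013 to 3063, 359 to 6070 and 40 to 1328 for Longan Arillus. They were 1240 to 2262, 850 to 2542 and 982 to 3415 for Zizyphi Semen, 2519 to 3318 for Soshiho-tang against Yijin-tang and 1019 to 1607 for Longan Arillus against Zizyphi Semen. Genes 2-fold apart in the single libraries, with 1 vehicle library left out, ran from 1974 to 2020, 88 to 130 and 124 to 202 for Polygalae Radix and from 1226 to 1414, 228 to 311 and 29 to 54 for Aucklandiae Radix. High against low dose gave 834 to 1022 genes for Yijin-tang, 2164 to 2284 for Soshiho-tang, 7292 to 7802 for Schisandrae Fructus, 90 to 107 for Longan Arillus and 556 to 867 for Zizyphi Semen. With the low dose as reference the counts were 1249 at the high and 4 at the medium dose of Yijin-tang, 3316 and 2 for Soshiho-tang and 0 and 0 for Liriopis seu Ophiopogonis Tuber. They were 7 at the medium dose of Schisandrae Fructus, 167 and 0 for Longan Arillus and 1031 and 0 for Zizyphi Semen. Without the low-count filter they were 1161 for Yijin-tang low, 1560 and 1323 for Soshiho-tang medium and low, 1456 and 1828 for Liriopis seu Ophiopogonis Tuber high and low, 1493 and 871 for Schisandrae Fructus medium and low and 1790 for Longan Arillus low. A fit of only the libraries compared gave 1657 for Yijin-tang low, 1733 and 1561 for Soshiho-tang medium and low, and 1997 and 7 for Liriopis seu Ophiopogonis Tuber high and low. It gave 1808 and 1128 for Schisandrae Fructus medium and low, 0 for Longan Arillus medium, 2003 for Zizyphi Semen low and 858 for Longan Arillus against Zizyphi Semen. The length and GC correction gave 1249 for Yijin-tang medium, 629 for Liriopis seu Ophiopogonis Tuber low and 2892 for Longan Arillus medium. Thinning to equal depth gave 281 for Yijin-tang low, 470 for Liriopis seu Ophiopogonis Tuber high and 122 for Schisandrae Fructus low, and DESeq2 gave 536 for Soshiho-tang low and 326 for Schisandrae Fructus low. A minimum of 1 CPM gave 3096, 327 and 427 genes for Polygalae Radix and 2465, 654 and 217 for Aucklandiae Radix at the high, medium and low dose. The estimated correlation left 52 list calls where the preset one gave 183, since it allows for genes of a list moving together, and the median correlation of the high minus low differences was 0.05 over all genes and 0.14 with at least 10 CPM. The replicate block left every named call in place and moved no count by more than 1.5 times. Between treated groups and the vehicle, and between the extracts compared directly, same-numbered samples had correlations of -0.54 to 0.57 with a median of 0.01. The replicate numbers thus showed no common pairing there. Same-numbered samples of different doses of one extract were not compared in this way, so pairing within a library set stays open. The signs that turned with the low dose as reference were those of EGR1 (0.09) for Yijin-tang, TIPARP (0.03) for Soshiho-tang, MKI67 (0.01) for Schisandrae Fructus, TUBA1B-AS1 (0) and FTH1 (-0.06) for Longan Arillus. For Liriopis seu Ophiopogonis Tuber they were C4orf48 (-0.09), MALAT1 (-0.04), EGR1 (0.07), HMCN1 (0.07), FAT1 (0.03), POMK (0.07), NFKBIA (-0.05), CCL2 (-0.04), COL3A1 (0.05) and SESN3 (0.06), and for Zizyphi Semen PAPPA-AS1 (-0.12), ACLY (0.11), ACACA (0.13), CEBPB (-0.03), NFKBIA (-0.11), COL4A2 (0.08), COL4A1 (0.08), MT-CO2 (-0.03) and CYP1A1 (-0.03). For the counts and signs that did not hold the cause was not tested.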

Other observations

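The adenine and MondoA tests, the length and GC correction, thinning, the medium dose against the low dose and leaving out libraries from the high against the low dose were chosen only after the result was seen. Some gene groups passed in no replicated high-dose group against the vehicle. Of 22 ribosomal protein genes 1 rose with Schisandrae Fructus (0 adjusted over the list alone) and none passed in the other 5 extracts by edgeR. The list's medians lay between 0.01 and 0.11, and its lowest adjusted p in camera was 0.129, for Soshiho-tang. The 22 nuclear genes of the respiratory chain had medians between -0.03 and 0.02 (lowest adjusted p = 0.228, Liriopis seu Ophiopogonis Tuber), with 6 up and 1 down for Schisandrae Fructus (3 and 1 adjusted over the list alone). The 15 TGF-beta and YAP targets came closest with Soshiho-tang (2 up and 6 down, 2 and 7 adjusted over the list alone, median -0.07, adjusted p = 0.0621) and the 10 glucocorticoid receptor targets with Schisandrae Fructus (3 up and 1 down, median -0.04, adjusted p = 0.171). Among markers of other cell types this held for 2 lists. The 6 haematopoietic markers had their lowest adjusted p with Longan Arillus (0.0643, median -0.17, 1 down, 2 adjusted over the list alone) and the 3 hepatocyte markers with Soshiho-tang (0.292, median -0.37, 1 down, 2 adjusted over the list alone).

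The single libraries differed from the vehicle at the lower doses too, given here as values without a test. Matrix genes had a median of -0.67 at 6 and -0.34 at 1.2 µg/mL of Polygalae Radix, where random lists had -0.07 and 0.01, and of -0.57 at 32 and -0.31 at 6.4 µg/mL of Aucklandiae Radix. Random lists were matched on expression and not on transcript length. These libraries had length correlations of -0.64 to -0.28, where the vehicle libraries had 0.37 to 0.65. The vehicle lay in another library set, so extract effects at these doses cannot be told apart from set or length differences. At high doses of replicated extracts, the matrix call against the vehicle held against the low dose only for Soshiho-tang. NRF2 targets had medians of 0.93, 0.39 and 0.24 from the high to the low dose of Aucklandiae Radix, and metallothioneins 1.96, 0.78 and 0.29, with MT2A at 1.08 at the medium dose. The 7 neuronal markers had a median of -1.23 at the high dose of Polygalae Radix, the 6 haematopoietic markers -1.84 and the 3 hepatocyte markers -2.12, each in the lowest 0.5% of random lists. Libraries of the replicated groups, each set against the vehicle in the same way, had 4 to 295 genes 2-fold apart at the high dose (median 40), 4 to 436 at the medium (median 11) and 1 to 84 at the low dose (median 6).

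Low-dose groups differed from the vehicle in 193 to 3297 genes and from each other in few. Transcript length ran with the vehicle set, whose libraries had correlations with length of 0.37 to 0.65 across genes where treated sets lay between -0.67 and 0.41. A length and GC correction kept a median of 56.5% of the low-dose calls (range 38.4 to 68.4%), so these went beyond the trend as fitted. The correction used the longest transcript of each gene and may leave part of the bias, so length and GC content stay open. Thinning to the smallest total kept a median of 67.8%, which argues against the lower depth of the vehicle as the whole cause. Low-dose groups within a library set differed in a median of 0 genes, which both a difference between library sets and a common effect of exposure would give. The vehicle stood alone in its set, so these cannot be told apart. The sample labels give a dimethyl sulfoxide content for the vehicle and none for the treated libraries, so they do not show an equal solvent content.

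The 7 named falls with Zizyphi Semen, CENPE, AKAP9, ANKRD12, GOLGA4, MKI67, CEP290 and GOLGB1, kept their call against the low dose after the length and GC correction (7 of 8, CENPE at -2.45 before and after) and at least 7 of 8 passed against the vehicle in every fit with 1 library left out. The kept calls after the correction argue against length bias as the whole cause, and RGPD5 had not passed before (adjusted p = 0.237). These genes were chosen for having every treated library below every vehicle library. That choice favours a kept call, so leaving out 1 library cannot decide whether 1 library deviated. Fewer dividing cells would lower all mitosis genes, but against the low dose the 14 shorter ones had a median of -0.04 and the longer ones of -0.17. A candidate explanation is a shift of adenine-rich transcripts: between high and low dose 41 of 50 genes with at least 36% adenine fell (82%, median -0.51), as did 4.1% of the rest of 9719 genes. Their medians between these doses in the other 5 extracts lay between -0.03 and 0.08. The idea came from the named falls, of which 6 are among these 50 genes, so the 42 with transcripts under 7000 nucleotides, which hold none of them, count for more: 33 fell and 0 rose against the low dose (median -0.42). The cutoff of 36% was also set after the result was seen and no other was tried, so these 42 genes are not free of that choice. Across all 9719 genes the rank correlation of the change with adenine content was -0.13, and -0.09 to 0.06 in the other 5 extracts. MKI67, with 32.9% adenine, is not adenine-rich, and its fall is not covered. As deviations from the mean of the group means, the 50 genes had medians of -0.58 to -0.26 in the high-dose libraries of Zizyphi Semen and of -0.05 to 0.22 in the other 48 treated libraries of replicated groups. Whether this arose in the cells or in the making of the libraries stays open, and no biological explanation beyond cell division was tested.

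TXNIP rose against the low dose with Yijin-tang (2.49), Schisandrae Fructus (4.97) and Longan Arillus (2.51), and ARRDC4, the other strong target of the sugar-sensing factor MondoA, rose with it in 3 of 3 (0.95, 2.39 and 0.95). With Soshiho-tang TXNIP rose by 1.11 against the low dose while ARRDC4 stood at 0.19 (adjusted p = 0.309). Lower PI3K signalling acting through FOXO would raise other FOXO targets, but in 0 of the 3 extracts did more of these 10 genes rise than fall against the low dose (0 up and 2 down, 2 up and 3 down, 0 up and 2 down). For Soshiho-tang 4 of them rose and 1 fell (median 0.22), so there this route stays open. Sugar brought by the extract into the galactose medium may act through MondoA; the extracts' sugar content is not known here, so this stays open next to other routes to MondoA.

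Other splits of the 6 libraries of a 3 against 3 comparison number 10 with the real one, too few for a share under 0.05. The real count was the largest, 1 of 10, in each of the 16 comparisons, and the highest other was 0 or 1 in all but 2. For the high dose of Schisandrae Fructus it was 2 against 8943, and for the medium dose of Longan Arillus it was 2886 against 4501, so a split of those 6 libraries that mixed vehicle and treated samples also called many genes.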
